A study of Drosophila melanogaster with 3 samples.

How the data were processed

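ChIP-seq peak lists of 3 biological replicates of whole embryos were analysed, all of 1 group. Coordinates are those of dm6, per the labels. The deposited lists came in ranked and thresholded forms, ordered by the irreproducible discovery rate (IDR), a measure of how well calls repeat between data sets. Peak height is the signal value that the authors' files give for each peak, and it was used to describe and rank peaks. The ranked lists deposited by the authors also give the -log10 of the IDR. All peaks of the thresholded lists had a -log10 IDR above 2, an IDR of at most 0.01. Each sample's lists were made from that sample's alignments and 1 further shared file, per the deposited notes on each sample, so the replicate lists are not fully independent of each other. The aligner, peak caller and read depth were not given in the sources used here. The ranked lists held 133175 calls in replicate 1, 155387 in replicate 2 and 133613 in replicate 3. Because depth is unknown, the precision of a single peak height could not be given. Intervals on shares of summits are exact Clopper-Pearson intervals at 95% and cover counting error only.

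The main list was the conservative thresholded list of the whole series. The other 3 thresholded lists of the whole series served as alternatives, because which data sets each one compares was not given in the sources used here. Tests used chromosomes 2L, 2R, 3L, 3R, 4, X and Y. Genes and TSSs came from Ensembl release 115 without transposable element genes, and sequence from the RefSeq release of the same assembly.

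Overlap between replicates needed at least 1 bp and was set against 1000 random placements on the same chromosome. Summits were assigned to promoters within 500 bp of any TSS, then to the 5' UTR, 3' UTR, coding exon, other exon, intron or intergenic class. Chromosome counts were tested with an exact binomial test on length without unknown bases. A gene's territory was the gene with 5 kb on each side. Each of 24 gene lists was compared with 10000 random lists of protein-coding genes matched on decile of territory length, where 0.0002 is the smallest raw p possible. Of the symbols in these lists, 3 were replaced by their current names and 1 was left out because it matches more than 1 gene. For 16 motifs and for all words of 6 bases, a window of 50 bp on each side of the summit was compared with windows centred 500 bp away. The exact McNemar test used 1 flank per summit, picked at random. For motifs, the flank shares and ratios given are means over both flanks, so they can differ from the contrast that was tested. The relation of height and motif used 100000 permutations. Tests were two-sided unless stated, and Benjamini-Hochberg adjustment was made within each family of tests. Errors are SDs over the same result computed on each replicate's own list. Correlations of height are across peaks. With 1 group there was no test between groups.

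Named genes followed a rule fixed before the data were examined, as were the gene lists, motifs, tests and alternative settings. It took the 20 highest main list peaks found in every replicate, up to 4 genes per list with the highest peaks, and hb, Kr, kni, gt, tll, eve and Ubx. Alternatives covered the overlap rule, peak list, peak height, promoter window, flanks, gene matching, motif window and each replicate left out. For results computed on the main list's summits, the main list was not called again without a replicate. The peaks of 1 remaining replicate list that overlap a peak of the other were used instead, 1089 to 1276 in number. A stricter IDR of 0.001, merging of overlapping peaks, the list of each single replicate and the removal of Cpr, Acp1 and Acp65Aa from lists taken by symbol were added after the data were seen, the first because the planned IDR of 0.02 was looser than that of the deposited lists.

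The procedures were tested on simulated data. Of 50 gene lists made rich in genes with peaks, 100% passed, and 4.2% of 500 random lists had p below 0.05. The planted lists were larger than most of the lists tested. Smaller lists and lists poor in genes with peaks were not simulated, so the power to find those is unknown. The Hb motif planted in 10% of 2000 random positions passed the test. Its share rose by the 10 percentage points planted, and smaller gains were not tried. At positions without the planted motif, 0 of 2080 words passed. A promoter share of 56.4% was recovered as 56.5%. An overlap of 59.9% was recovered as 60.3%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.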

Results

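Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos aged 0 to 24 hours labelled as carrying Hunchback (hb) fused to eGFP, a green fluorescent protein used here as a tag. Hunchback is a zinc-finger transcription factor of the gap gene class. An antibody against GFP was used for the pull-down. The series held 1 group of 3 biological replicates, so every comparison was made between replicates, or between peaks and the genome. The libraries are called by their label, hb-eGFP, throughout. Read depth was not given in the sources used here, and whether the number of peaks follows it was not tested.

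The deposited thresholded lists held 1391 peaks in replicate 1, 2093 in replicate 2 and 1476 in replicate 3, a mean of 1653 ± 383 (SD, n = 3). The main list, called over all 3 replicates, held 2184 peaks. Of these, 2137 lay on the 7 main chromosomes and were used below. Median peak height, the signal value given by the authors, was 82.8 in replicate 1, 122 in replicate 2 and 77.6 in replicate 3, and 227 in the main list. The median width of a main list peak was 464 bp.

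The replicate lists shared most of their peaks. In replicate 1, 1186 of 1331 peaks (89.1%) overlapped a peak of replicate 2 and 1089 (81.8%) a peak of replicate 3. In the longer list of replicate 2, 58.5% of peaks were found in replicate 1 and 61.5% in replicate 3. Over the 6 ordered pairs the mean was 76.0% ± 13.2 (SD), against 0.779% for peaks placed at random on the same chromosome (one-sided permutation p = 0.001, the smallest that 1000 placements can give). Of the main list, 1068 of 2137 peaks overlapped a peak in all 3 replicate lists. Across 2060 main list peaks with a height in each replicate, Spearman's rho of height was 0.859 between replicates 1 and 2, 0.850 between 1 and 3, and 0.830 between 2 and 3. Peaks are not independent replicates, and no p was computed for these values. The main list had been kept by IDR, which favours calls that repeat, and 77 peaks without a height in each replicate were left out. Part of this agreement can therefore come from the selection of peaks.

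The highest peaks lay almost all at promoters. The highest of all was at MESK2 (FBgn0043070) on chromosome 2R, from 21501778 to 21502204 in dm6 coordinates, with a height of 2533.1 and its summit 76 bp upstream of the transcription start site (TSS). It ranked 1 in each of the 3 replicates, where ranks count calls on the main chromosomes only. The peak at Rpn6 (FBgn0028689), which encodes a subunit of the proteasome lid, lay on 2R from 14752185 to 14752583, had a height of 1782 and ranked 2 on the main chromosomes in each replicate. Next came the promoter of the ubiquitin ligase gene Ube3a (3L, 11210436 to 11210830) at 1613 and that of the ribosomal protein gene RpL32 (3R, 30046075 to 30046465) at 1576. The peak nearest to org-1, a T-box gene, had a height of 1562 and lay in an intron on X, from 8452193 to 8452547. Among the 20 highest peaks found in every replicate, 19 were in promoters, among them those at RhoGAP93B, Capr, jagn, Daxx, milt, hts and Pym. The word TATCGA stood within 50 bp of 15 of these 20 summits, and the Hunchback (Hb) motif at 0 of them. In the whole main list these shares were 47.3% and 4.31%, so a count of 0 among 20 summits says little about the Hb motif.

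Promoters held 1786 of the 2137 summits (83.6%), 6.12 times the 13.6% of random placement. In the replicate lists the promoter share was 89.1% ± 4.01 (SD, n = 3). Introns held 6.50% of summits against 39.6% at random, intergenic sequence 5.19% against 27.0%, and coding exons 3.37% against 13.1%. All 7 classes passed the two-sided permutation test (adjusted p from 0.0028 to 0.012 over 1000 placements). The median distance from a summit to the nearest TSS was 64 bp. Of summits within 500 bp of a TSS, 71.2% lay upstream of it. With TSSs of protein-coding genes only, the class of other exons turned from lower to higher than random, at 2.81% of summits.

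**Figure D1:**
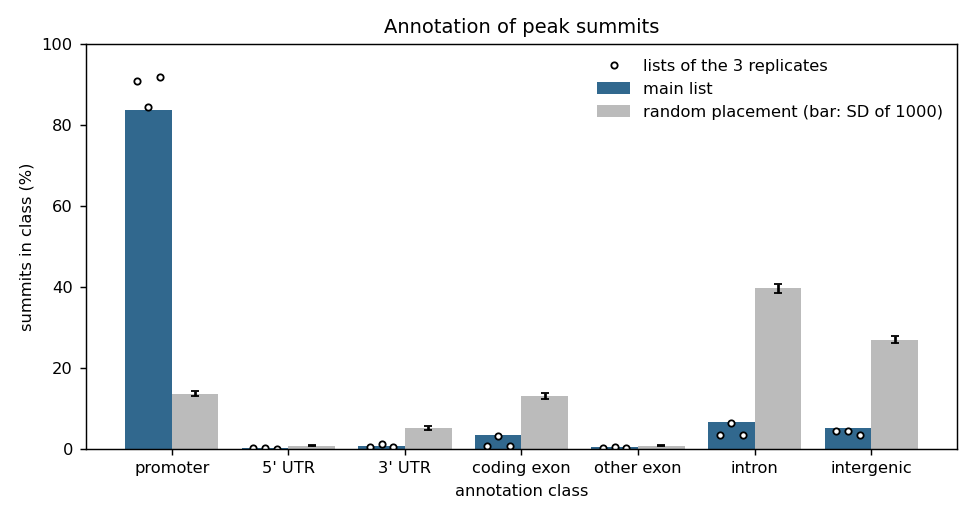
Share of peak summits (percent, vertical axis) in each annotation class (horizontal axis) for the main list (blue bars), the lists of the 3 replicates (points) and random placement (grey bars, with the SD over 1000 placements). Promoters hold 83.6% of main list summits against 13.6% at random, and the replicate lists lie at 84.5% or above.

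Peaks were unevenly spread over chromosomes. The X held 415 peaks where its length predicts 366, a ratio of 1.13 (adjusted p = 0.010, exact binomial test). Chromosome 3L, the small chromosome 4 and the largely heterochromatic Y were below expectation, with ratios of 0.873, 0.289 and 0.019 (exact binomial adjusted p = 0.0062, 0.00086 and 3.9e-21). In the replicate lists the ratio was 1.22 ± 0.0891 for the X and 0.837 ± 0.0593 for 3L (SD, n = 3). Both calls depended on the peak list. In the whole-series list of 3696 peaks, chromosome X, observed over expected, stood at 0.840, and chromosome 3L, observed over expected, at 1.00.

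The tagged gene and the other gap genes named beforehand had no summit in the main list within 5 kb. These were hb (FBgn0001180, 3R, 8690980 to 8697822), Kr, kni, gt and tll, and the pair-rule gene eve had none either. The lists of replicates 2 and 3 each held 1 summit near hb and that of replicate 1 held 0. In the ranked lists, which also hold weak calls, the highest peak near hb stood at the 58.4 ± 3.62 percentile of genes of like territory length (SD, n = 3). Near gt that percentile was 11.8 ± 4.54, near kni 31.4 ± 8.36 and near tll 35.5 ± 19.0. It was 37.3 ± 26.2 near eve and 77.8 ± 2.08 near Ubx. Near Kr it was 3.65 ± 6.32, where replicates 2 and 3 had no call and were counted as 0. Percentiles of single genes were not computed with genes matched on intergenic flank length. That matching moved the median for 21 gap and temporal genes from at most percentile 0.85 to 33.4, 57.4 and 44.2 in replicates 1, 2 and 3. Of the Hox gene Ubx, 1 summit lay in the territory, with a height of 219, but its nearest TSS was that of modSP.

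Of 13968 protein-coding genes, 5121 (36.7%) had a summit in the gene or within 5 kb. Ribosomal protein genes had one more often than random genes matched on territory length: 57 of 92 (62.0%) against 32.5% (permutation, adjusted p = 0.0016). The highest were at RpL32, RpS27 (969), RpS13 (949) and RpS7 (778), although the peaks counted for RpS27 and RpS13 lay at the promoters of their neighbours Nup358 and Pp2A-29B. Chemoreceptor genes, which encode odorant, gustatory and ionotropic receptors, had one in 21 of 179 cases (11.7% against 36.5%), and cuticle protein genes in 8 of 121 (6.61% against 30.2%), both with a permutation adjusted p = 0.0016. The cuticle list was taken by gene symbol and held Cpr, a P450 reductase gene with a summit. Without it, a change made after the data were seen, 7 of 120 cuticle protein genes (5.83% against 30.1%) had a summit, at the same adjusted p. These 3 lists passed the threshold in each replicate, with 49.6% ± 3.32, 11.2% ± 2.96 and 3.58% ± 3.34 of their genes near a summit (SD, n = 3). Neighbouring genes with overlapping territories can share a summit, as Ir60d and Ir60e did, and RpS14a and RpS14b. The tests of gene lists counted each gene on its own, so their p-values do not allow for such neighbours.

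Gap and head gap genes (1 of 16, permutation adjusted p = 0.024) and differentiated neuron genes (1 of 15, permutation adjusted p = 0.023) were also below matched lists. The single members were cnc, with a summit in its intron, and Syt1, whose higher peak lay at the promoter of Taf10b. Neither call held with random genes matched on intergenic flank length (permutation adjusted p = 1 and 0.15). Neither held with each summit given to the nearest TSS, where 0 of 15 neuron genes still did not pass (permutation adjusted p = 0.61). For lists of this size, that setting could therefore not give a lower call. Both calls were also lost in peaks found in every replicate, and when any replicate was left out. Those sets held 1068 to 1276 peaks, and whether their smaller size alone lost the calls was not tested. Both calls held in the whole-series lists of 2019 and 1846 peaks but not in that of 3696. Among the replicate lists, the call for gap genes passed in 2 and that for neuron genes in 1. Neuroblast temporal factors, with 0 of 9, did not pass (permutation adjusted p = 0.062, and 0.053 when computed exactly, a check added after the data were seen). The other 18 lists did not pass either. They included Hox genes (4 of 8), pair-rule genes (4 of 12), segment polarity genes (3 of 15), dorsoventral genes (3 of 18), maternal axis and terminal genes (3 of 7), glia genes (4 of 11), germ cell genes (6 of 10) and zygotic genome activation genes (5 of 16). Neuroblast and neuronal precursor genes stood at 3 of 15, muscle and mesoderm regulators at 3 of 13, muscle structural genes at 4 of 20 and endoderm and gut genes at 2 of 11. Tracheal and ectodermal organ genes stood at 2 of 12, blood and fat body genes at 3 of 11 and early, pioneer or chromatin regulators at 4 of 13. Heat shock genes had 6 of 19, proteasome subunit genes 23 of 48 and accessory gland and seminal fluid genes 4 of 47. With each summit given to the nearest TSS, proteasome subunit genes passed as higher (15 of 48, 31.3% against 13.2%, permutation adjusted p = 0.0048) and accessory gland genes as lower (0 of 47, permutation adjusted p = 0.011). The accessory gland list, also taken by symbol, held the adult cuticle protein genes Acp1 and Acp65Aa. Without them it stood at 4 of 45 (permutation adjusted p = 0.14), and at 0 of 45 by nearest TSS (adjusted p = 0.015). Of 74 named genes with a summit in their territory, the highest peak lay nearest to the TSS of another gene in 49.

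**Figure D2:**
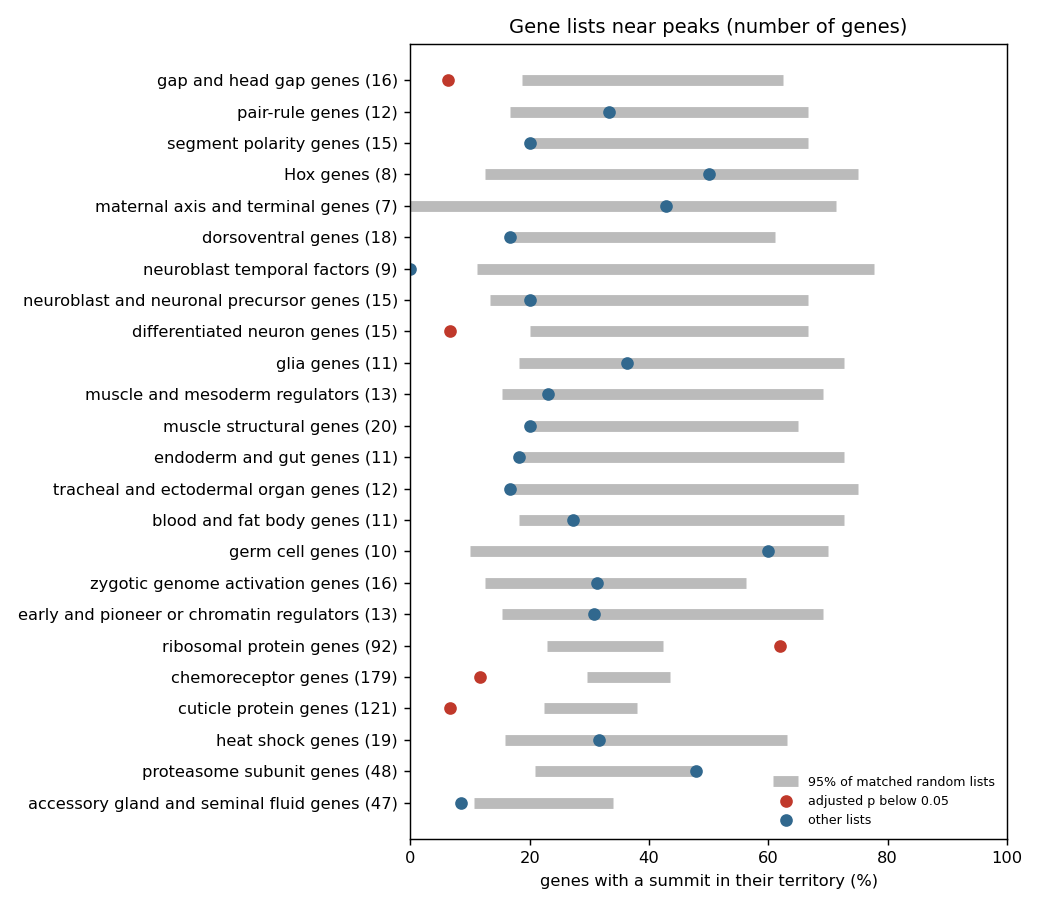
Percent of the genes of each list with a summit in their territory (horizontal axis), with the number of genes in parentheses. Grey bars span 95% of 10000 random lists matched on territory length, red points have an adjusted p below 0.05 and blue points do not. Ribosomal protein genes stand at 62.0%, to the right of their bar, and chemoreceptor and cuticle protein genes at 11.7% and 6.61% (Cpr included), to the left of theirs.

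The Hb motif, MATAAAAA on either strand, was not enriched at summits beyond its reversed control. It stood within 50 bp of 92 of 2137 summits (4.31%, exact 95% interval 3.48 to 5.25), against 3.88% in windows 500 bp away, a ratio of 1.11 (adjusted p = 0.79, exact McNemar test). The same motif reversed, a control for base composition, stood at 5.29% of summits. In each replicate list the Hb motif stood above its flanks, at 4.81% against 3.31% in replicate 1, 5.35% against 3.98% in replicate 2 and 4.30% against 3.51% in replicate 3, without passing the test. The reversed control did so too, with a mean of 5.39% ± 0.279 at summits and 4.15% ± 0.342 in flanks (SD, n = 3). The palindrome TATCGATA, known as the site of the factor DREF, stood at 20.5% of summits against 0.491% of flanks (exact McNemar adjusted p = 1.3e-116) and at 22.3% ± 3.17 in the replicate lists. GGTCACAC, known from Motif 1 binding protein, stood at 3.51% against 0.351% (exact McNemar adjusted p = 7.3e-14), and CA repeats were lower at 1.03% against 3.16% (adjusted p = 4.0e-05). The motifs of Zelda, Bicoid, Kruppel, Giant, Tailless, Caudal, Twist, GAGA factor and Odd-paired did not pass the test. Against random positions of the same annotation class, the motifs of Bicoid (ratio 0.506, exact McNemar adjusted p = 0.0010) and GAGA factor (ratio 0.444, adjusted p = 0.031) passed as lower. In a window of 100 bp the Hb motif passed, with a ratio of 1.39 (exact McNemar adjusted p = 0.026), but so did the reversed control, where motif Hb_reversed, centre over flank, reached 1.5 (adjusted p = 0.00032).

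**Figure D3:**
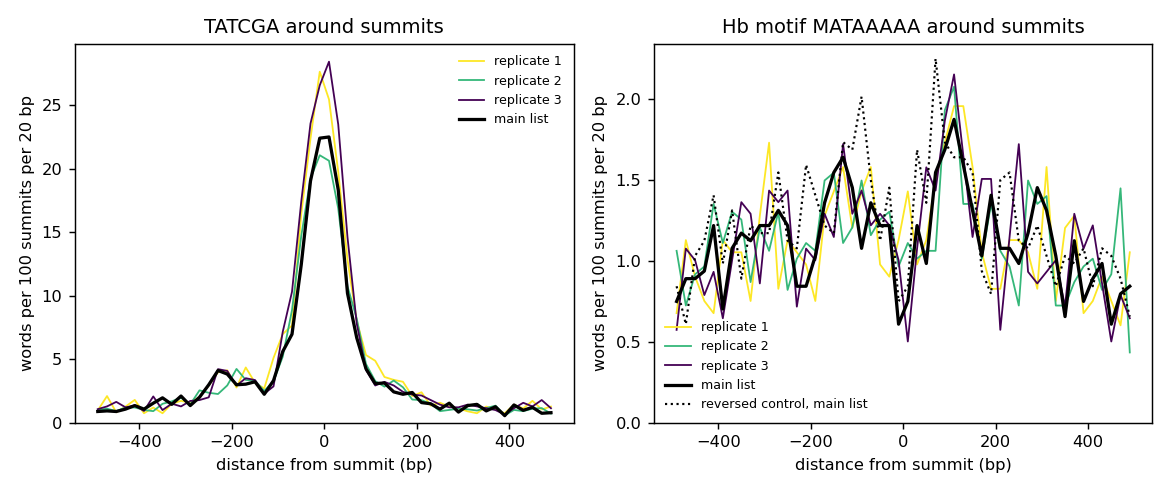
Number of words per 100 summits in 20 bp bins (vertical axis) against distance from the summit in bp (horizontal axis), for TATCGA (left) and the Hb motif (right), in the main list (black) and the 3 replicate lists (coloured). The dotted line is the reversed control. TATCGA peaks at the summit, where 47.3% of main list summits carry it within 50 bp, and the Hb motif does not.

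Among all 2080 words of 6 bases, 188 were higher and 284 lower at summits than in flanks. The leading word was TATCGA, at 47.3% of summits against 3.37% of flanks (exact McNemar adjusted p = 1.8e-231), and at 52.2% ± 6.59 in the replicate lists (SD, n = 3). It was followed by ATCGAT, at 42.8% against 3.42%, and CGATAG, at 38.7% against 2.43%. Of the 25 leading words, 13 held CGATA, TATCG, ATCGA or TCGAT.

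The Hb motif share did not follow peak height: from the highest 535 peaks to the lowest 534, in 4 groups, it was 3.93%, 5.81%, 4.31% and 3.18% (Spearman's rho across peaks 0.023, permutation p = 0.30). In the peaks shared by replicates 2 and 3, the motif share against peak height gave a rho of -0.065 (permutation p = 0.019).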

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

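The tests of a wrong label and of another protein were chosen after the words at summits had been seen. So were matching on intergenic flank length and the ratio without duplicate gene copies. The other tests of this part were written before they were run. Among them, the test of unspecific pull-down used TATCGA, which the word search on these same peaks had found.

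Some calls passed an IDR of 0.01 in the ranked lists but were missing from the thresholded lists, and lie outside the comparisons of the report. Their number was 113 in replicate 1, 84 in replicate 2 and 90 in replicate 3. On scaffolds other than the main chromosomes lay 52, 15 and 36 of them. In replicates 1 and 3 the highest was on an unplaced scaffold, at 450 and 543, the place 2 call of each ranked list when all scaffolds are counted. In replicate 2 it lay on 3R from 17718247 to 17718540, at 672.

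In libraries labelled hb-eGFP, summits sat on TATCGA words at promoters, without an excess of the Hb motif over its reversed control or of gap genes. A wrong label on 1 library alone would not account for the whole pattern, since TATCGA was at least 10.9 times as frequent at summits as in flanks in each replicate. These values do not test whether the label of any library is right, and the replicate lists are not fully independent of each other. Unspecific pull-down at active promoters cannot be told apart from binding tied to TATCGA, because activity was not measured: among ribosomal protein and proteasome promoters, 44 of 51 with a summit carried TATCGA against 34 of 89 without one, a ratio of 2.26 (Fisher's exact p = 2.0e-08), and 2.20 without 21 duplicate gene copies, but active promoters that carry TATCGA more often would give the same. A DNA-binding protein other than Hunchback in all 3 libraries and Hunchback brought there by another protein cannot be told apart either, since the Hb motif at no more than 0.982 times its reversed control restates the pattern and does not test it. Whether Hunchback signal was diluted by other cells of these whole embryos stays open, because the outcome turned on the matching: the median of the highest peaks of 21 gap and temporal genes was at most at percentile 0.85 with genes matched on territory length, but at percentiles 33.4, 57.4 and 44.2 with genes matched on flank length.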

How the results depend on the processing

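Alternatives with the list of a single replicate, merged peaks, gene lists without members of other families or an IDR of 0.001 were chosen after seeing the data. The overlap of replicate peak lists and, in the annotation of peak summits, the promoter share kept their direction and side of the threshold under every alternative run, with overlaps from 66.3% to 80.1% and promoter shares from 61.5% to 96.4%. The number of chromosomes past the threshold stayed between 4 and 6, but not always the same ones: 2L and 2R passed in the lists of 1846 and 3696 peaks. At an IDR of 0.001 the mean number of peaks per replicate was 859. The peak height agreement between replicates moved to 0.726 in the whole-series list of 3696 peaks and 0.787 in the higher part of the peaks, and from 0.830 to 0.859 without 1 replicate. Places in the ranked lists gave a Pearson r of 0.468. Of gene lists near peaks, 10 passed in the list of 2019 peaks and 9 in that of 1846, but 3 in that of 3696, in peaks found in every replicate, in the higher part of the peaks and without any 1 replicate. Segment polarity, dorsoventral and blood and fat body genes passed as lower in both of the first lists, neuroblast temporal and accessory gland genes in the list of 2019 and muscle structural genes in that of 1846. Among named motifs at summits, the ratio of the Hb motif was 0.899 in the list of 3696, 0.864 in a 25 bp window, 0.935 for the shorter core and 1.39 in a 100 bp window, where 305 words passed. It was above 1 in the other settings, with 1.21 in the list of 1846, 1.45, 1.35 and 1.22 in the lists of replicates 1, 2 and 3, and from 1.33 to 1.53 without 1 replicate, and passed only in the 100 bp window. The shorter core passed as lower in the list of 3696, where motif Hb_short, centre over flank, was 0.813. The Bicoid motif passed as lower in the lists of 2019 and 3696 peaks and the GAGA factor motif in that of 1846, and both did so in peaks found in every replicate. The motif share against peak height had a rho of -0.047 in peaks found in every replicate, -0.043 in the higher part and -0.023 for the shorter core, -0.030 and -0.034 in the lists of replicates 2 and 3, and from -0.065 to -0.013 without 1 replicate. The calls for ribosomal protein, chemoreceptor and cuticle protein genes held under every alternative run. Among single items, 1574 alternatives left the result as it was, 550 moved a value without changing a call, 37 brought a result past the threshold and 27 took one back. Another 4 reversed: the ratios of chromosomes 3L (1.00) and X (0.840) in the list of 3696, other exons with protein-coding TSSs (2.81%), and, in a 100 bp window, motif polyA, centre over flank (1.24). The cause was not tested in these cases, and unknown read depth limits how far any missing peak can be read.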

Other observations

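The test of added gene families was chosen after the highest peaks had been seen. The other tests of this part were written before they were run. Those on TATCGA and CGATA used words that the word search on these same peaks had found.

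Summits lay between divergent genes more often than random promoter positions. Of 1689 summits at protein-coding promoters, 40.8% lay between TSSs facing apart within 500 bp, against 23.4% for random TSSs at the same offsets (one-sided permutation p = 0.001, the smallest possible). In the replicate lists 43.7%, 39.6% and 42.6% did so. Near tRNA genes, 77 summits lay within 500 bp of 1 of 290 genes, against 3.70 for random placement (one-sided permutation p = 0.001). The placement was not matched on promoters. Mitochondrial ribosomal protein genes (45 of 73 against 20.6 in matched lists, permutation adjusted p = 0.0012) and vacuolar sorting genes (18 of 27 against 10.6, adjusted p = 0.021) had summits more often than matched genes. The hypothesis that at least 3 of the 6 added families would pass was not borne out, since 2 did. Translation initiation factor genes (19 of 44), aminoacyl-tRNA synthetase genes (19 of 33), nucleoporin genes (13 of 21) and Rab GTPase genes (19 of 36) did not pass.

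TATCGA followed peak height. It stood at 66.7% of summits in the 535 highest peaks and 12.4% in the 534 lowest, with a Spearman's rho across peaks of 0.401. The number of CGATA words within 100 bp rose from 0.704 per summit in the same lowest peaks to 3.08 in the highest, with a rho of 0.530. Both had a permutation p of 1e-05, the smallest possible, which treats peaks as independent although they are not independent replicates. Height was not compared within promoters alone, where TATCGA stood at 54.7% of main list summits against 9.40% outside.

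Peaks of 1 replicate list only carried TATCGA less often than peaks of all 3 lists. The shares were 19.8% against 59.1% in replicate 1, 25.8% against 57.2% in replicate 2, and 32.5% against 62.5% in replicate 3 (Fisher's exact p of at most 4.7e-10). Location went with it: 42.6%, 65.7% and 72.5% of the peaks of 1 list lay in promoters, against 96.4%, 96.5% and 96.4% of those of all 3. In the main list TATCGA stood at 54.7% of summits in promoters and 9.40% of those outside. Of the 1068 main list peaks found in all 3 replicates, 904 lay in the higher part of the peaks. The shares were not compared at equal location or equal peak height.

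The hypothesis that summits outside promoters carry the Hb motif was not borne out. It stood at 7 of 351 such summits (1.99%) against 4.56% of flanks, a ratio of 0.438 (exact McNemar p = 0.015, adjusted p = 0.078). The controls for base composition also had lower shares at the same summits than in flanks. The ratio was 0.506 for the A homopolymer (exact McNemar p = 0.014, adjusted p = 0.078). For the reversed motif it was 0.585, but the test gave no difference (exact McNemar p = 0.69).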
